A study of Mus musculus with 2 samples.

How the data were processed

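Bone marrow cells of 5-month-old mice were sorted as lineage-negative Sca1+ CD117+ (LSK) cells and profiled with the 10x Genomics Chromium 3' v2 assay, per the labels' protocols. There were 2 libraries, 1 from mice with floxed Rxra and Rxrb alleles (control) and 1 from mice that also carried Vav-iCre (deleted). The number of mice behind each library is not given in the sources used here. The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell, whole numbers that the authors had not normalised, per the file headers and the values. Cell Ranger 2.2.0 and the builds mm10 and hg19 are named in the submitters' processing notes without a role, and the aligner settings, annotation release and cell filter are not given in the sources used here. Gene IDs are mouse IDs. Of 28692 genes, 28416 (99.0%) had their ID in the GENCODE M21 annotation of the mm10 build, from which coordinates were taken, with the first base numbered 1.

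The deposited cluster tables give the authors' class of each cell, made with ICGS2 per the first line of the table: 12 clusters over 8967 cells, and 4 sub-clusters of the HSCP-MPP class over 2096 cells, with 1 cell whose library field was blank. These classes were used as named by the authors. A clustering of the present work had been planned as the main source of classes; since cell types were to come from a deposited annotation where a file gives one, the planned clustering is an alternative instead. Of the HSCP-MPP cells used, 102 control and 81 deleted cells had no sub-cluster.

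Cells with fewer than 500 genes or more than 10% mitochondrial UMIs were left out, 7 in the control and 2 in the deleted library. Doublets were scored with Scrublet as run by scanpy, which called 0 in both libraries and so had not worked; no cell was removed as a doublet, and cells of more than 1 type can remain. Cells with at least 6 Xist UMIs were called female and those with at most 2 male. UMIs were summed over the cells of a library or class and given as CPM of all UMIs of the same cells. The CPM intervals are exact Poisson, those of ratios exact conditional binomial and those of shares exact Clopper-Pearson intervals, all at 95% and for counting error only. With 1 library per group no test between groups was possible, and cells were not used as replicates. Genes at least 1.5-fold apart with at least 20 CPM in either library (50 CPM within a class) are counted as higher or lower, as a description of size. To rank genes, a count of 0 was set to 3 counts over the cells of the library; no such fold is printed.

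The lists, markers, thresholds, the rule for named genes and 32 alternatives were fixed before the data were examined. That rule names Rxra, Rxrb and Rxrg, the 12 highest and 12 lowest folds at 50 CPM or more in LSK cells, 8 and 8 at 100 CPM or more in the stem cell class, 4 and 4 in each other class with at least 100 cells per library, and for a list up to 4 members with the largest folds and its most abundant member. It leaves out mitochondrial, ribosomal and unnamed gene models and the sex genes. Some genes that meet it are not reported here, though counts and list medians include them. Which lists the text leads with, and which members of a list it prints, were chosen after values were seen. The shares of UMIs held by 10 cells were computed for 23 genes picked after their values were seen.

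There were 32 gene lists and 14 marker lists of cell types. A list was measured with at least 5 members at 10 CPM (20 CPM within a class) in either library. Its median log2 fold was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and lies apart when beyond the 2.5 or 97.5 percentile. Intervals of medians came from 500 Poisson redraws of the counts. The B cell, T or NK cell, innate lymphoid precursor, monocyte or macrophage, mast or basophil, mature erythroid and endothelial or stromal lists had too few members at that level in LSK cells and are given as summed CPM. Class-standardised folds use the control's class shares for both libraries, and list members were then chosen by class-standardised CPM. For cell cycle, each cell was thinned to 3000 UMIs and called above the limit when its list UMIs exceeded the 90th percentile of control HSCP-MPP cells, 6 UMIs for both lists; 3.97% and 4.73% of those cells lay at the limit of the S-phase and G2M lists.

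Class sizes were compared where no leading gene, among the 10 with the largest fold over other cells, lay at least 1.5-fold apart between libraries in class-standardised folds, which left S-phase, M-phase and Mitotic M-M-G1. HSCP-MPP and LMPP were compared beside clusters made without genes that differ, and 7 classes were not compared. Of the sub-clusters, 1 met this rule and 3 were not compared. This selection was made after the shares were seen. LMPP and 5 smaller classes had fewer than 100 control cells, so the rule named no genes in them.

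Own clusters came from both libraries together (counts scaled to 10000 per cell, log-transformed, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.8, seed 0), with 7 other settings. They were named from the fixed markers. The naming rule was set on the data, after names and cell counts per library had been seen: 3 rules were tried, and the last requires 3 markers at 20 CPM or more, a mean log2 of at least 0.5 over other cells and no other class with more markers among the 10 leading genes. Clusters left unnamed held 57.6% of control and 51.3% of deleted cells at resolution 0.8, and 60.7% and 56.6% when genes that differ and cell cycle genes were left out.

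The fold and list steps were tested on simulated counts drawn from the real means with 200 changed genes. These counts were Poisson, with no spread between cells or mice, so the check covers the computation and not the spread of real data. For LSK cells, over 4714 genes, 100% of genes changed 1.8-fold and 99% of those changed 2-fold were recovered, 0 of 4515 unchanged genes passed the size rule, and intervals covered the true fold for 95.1% of genes. For HSCP-MPP cells, over 2155 genes, recovery was 100% and 98%, 0 of 1957 unchanged genes passed, and coverage was 95.3%. A planted list of 15 genes reached percentile 100 in both, and 8% and 0.5% of 200 random lists fell outside the central range. Alternatives covered scaling, cell and gene filters, size rules, class sources, cluster settings and thinning; 4 were added after the data were seen. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.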

Results

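Single-cell RNA profiles were collected from bone marrow LSK cells of 5-month-old mice. LSK cells lack lineage markers and carry Sca1 and CD117, so the sort holds the blood stem cells and the multipotent progenitors. The control library came from mice with floxed Rxra and Rxrb alleles, and the other library from mice that also carried Vav-iCre, a recombinase driven in blood cells, and is called the deleted library here. Rxra and Rxrb code for retinoid X receptors, nuclear receptors that bind DNA as partners of the retinoic acid, LXR, PPAR, vitamin D and thyroid hormone receptors. The series title names the fitness and quiescence of blood stem cells, so the comparison asks which genes, gene groups and progenitor classes differ between LSK cells with and without the recombinase. Each group had 1 library, so no difference below has a replicate check. All intervals are 95% and cover counting error only.

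The control library held 4585 barcodes, of which 4578 were used, with 36918449 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule) and a median of 7025 per cell. The deleted library held 4382 barcodes, of which 4380 were used, with 41324391 UMIs and a median of 8011.5 per cell. Median genes per cell were 1997 and 2229. The libraries also differed in sex. Xist, the RNA that silences an X chromosome in female cells, had 23687 UMIs in the control and 5 in the deleted library, and Xist counts per cell split the control into 1003 female cells, 3548 male cells and 27 unclear ones. All 4380 deleted cells had male counts. Values against the male control cells alone are given beside some of those below.

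The floxed genes were read first. Rxrb, on chromosome 17 from 34031812 to 34038399 (mm10), had 2005 UMIs in the control and 1481 in the deleted library, or 54.3 and 35.8 CPM (UMI counts scaled to the same total in both libraries), a log2 fold of -0.60 (-0.70 to -0.50). Rxra, on chromosome 2 from 27676440 to 27762957, had 84 and 80 UMIs, or 2.28 and 1.94 CPM, and no difference was detectable at this depth (log2 -0.23, -0.69 to 0.23). Rxrg, the family member that was not floxed, had 1 and 9 UMIs, a log2 of 3.01 with an interval from 0.16 to 8.46. The assay counts transcript 3' ends, which may lie outside the deleted exons, so these levels do not check the deletion.

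Among the authors' classes that were compared, a smaller share of the deleted library was placed among stem-like cells. A larger share fell in the lymphoid-primed, M-phase and Mitotic M-M-G1 classes. HSCP-MPP, the class of stem cells and early multipotent progenitors, took 28.8% of control cells (27.5 to 30.1) and 21.9% of deleted cells (20.7 to 23.2), a share ratio of 0.761 (0.70 to 0.83) that was 0.801 against male control cells. LMPP, the lymphoid-primed multipotent progenitors, took 2.01% (1.62 to 2.46) and 5.62% (4.95 to 6.34), a ratio of 2.79 (2.19 to 3.59). Mitotic M-M-G1 cells took 3.98% and 5.94%, a ratio of 1.49 (1.23 to 1.81), and M-phase cells took 7.21% and 8.72%, a ratio of 1.21 (1.04 to 1.41). The S-phase class was nearly equal at 23.6% and 23.7%. Within the control library, HSCP-MPP took 27.4% of male and 33.9% of female cells, and LMPP 1.94% and 2.29%. The deleted shares of both lay outside the intervals of either sex. M-phase took 6.71% of male and 8.97% of female control cells (7.28 to 10.9), and Mitotic M-M-G1 3.83% and 4.49% (3.29 to 5.96). For both of these classes the deleted share lay above the male interval but within the female one. M-phase is the authors' name, and its leading genes are mostly histone genes, with Tk1 and Esco2 among the rest. Its control cells had 4043 CPM of the S-phase list and 6466 CPM of the G2M list, beside 3680 and 2422 CPM in the S-phase class. A larger M-phase share is thus not read as more cells in mitosis. Among the leading genes of LMPP, 5 of 10 lay at least 1.5-fold apart between the libraries within classes, Dntt and Il7r among them, and 1 of 10 did so in HSCP-MPP, Iglc1. Clusters made without genes that differ between the libraries, and without the cell cycle lists, gave a share ratio of 0.760 (0.69 to 0.84) for HSC-like cells and a smaller ratio of 1.68 (1.49 to 1.90) for lymphoid-primed-like cells, which took 9.24% and 15.5% of cells; in the other own clusterings this second ratio lay between 1.23 (1.10 to 1.38) and 2.22. More lymphoid-primed cells and higher lymphoid genes in similar cells are not separated by these shares. Sizes of the other 7 classes were not compared, since their leading genes differed, as did 5 of 10 in LMPP. Of these 7, MPP Ier3-high took 15.8% of control and 12.4% of deleted cells, and MPP Ccl3-high 13.2% and 13.9%. Shares were 1.49% and 2.37% for proNeu-1, 0.55% and 1.26% for eMono and 1.44% and 1.92% for DC cells. The macrophage class took 1.29% and 1.67%, and preNeu cells 0.68% and 0.53%.

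**Figure D1:**
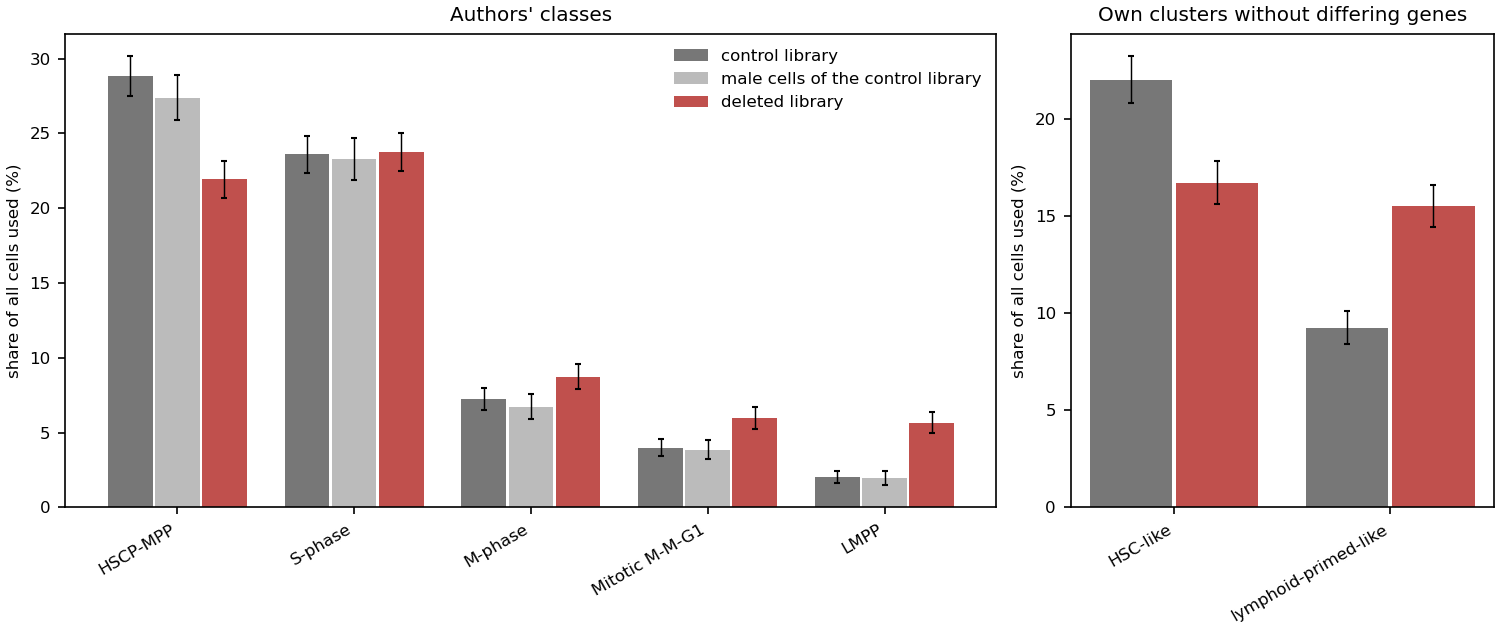
Share of all cells used (%) in each class, with exact 95% intervals as bars; the left panel gives 5 of the authors' classes in the control library, its male cells and the deleted library, and the right panel gives clusters made without genes that differ between the libraries. HSCP-MPP stands at 28.8% in the control and 21.9% in the deleted library, and LMPP at 2.01% and 5.62%.

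Of 4791 genes with at least 20 CPM in either library of all LSK cells, 39 lay at least 1.5-fold higher and 30 at least 1.5-fold lower in the deleted library, and against male control cells 33 of the 39 and 25 of the 30 did so again. With class shares held at those of the control 21 lay higher and 20 lower, and with totals that leave out mitochondrial and ribosomal genes 57 lay lower. Within the control library, 7 genes lay at least 1.5-fold higher and 39 lower in female than in male cells. Glo1, which detoxifies methylglyoxal made in glycolysis, had 80.4 and 183 CPM (log2 1.19, 1.13 to 1.25). Dntt, the terminal transferase of early lymphoid cells, had 142 and 307 CPM (1.12, 1.07 to 1.16). The antigen Ly6d had 43.3 and 83.1 CPM (0.94) and galectin 1, from Lgals1, had 299 and 531 CPM (0.83). Tropomyosin 4 from Tpm4 (0.82), Ms4a6c (0.79), the arginine synthesis enzyme Ass1 (0.76), the lectin receptor Clec12a (0.75), the chemokine Ccl9 (0.67) and S100a4 (0.67) were also higher. With class shares held at those of the control, Glo1 (1.19), Dntt (0.65), Ass1 (0.62) and Tpm4 (0.59) lay at least 1.5-fold higher, and Lgals1 (0.57), Ccl9 (0.52), Ms4a6c (0.47), Ly6d (0.44), Clec12a (0.35) and S100a4 (0.30) did not. Glo1 lies on chromosome 17 from 30584936 to 30626871 and Dntt on chromosome 19 from 41029275 to 41059525. The basophil proteases Prss34 and Mcpt8 had the largest folds, with 40 and 4240 UMIs for Prss34 (log2 6.57, 6.12 to 7.05) and 238 and 3044 UMIs for Mcpt8 (3.51, 3.32 to 3.71). These came from few cells: in the deleted library 10 cells held 78.3% of Prss34 UMIs and 60.7% of Mcpt8 UMIs.

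Lower in the deleted library was the neuropeptide receptor subunit Ramp1, with 420 and 254 CPM (log2 -0.72, -0.76 to -0.69). Sdsl (-0.61), Rxrb itself and Wdr89 (-0.59) also passed the size rule; Wdr89 has near-identical copies and is uncertain. Igha (-0.53), Def8 (-0.51), Mpnd (-0.47) and Txnip (-0.47), a brake on glucose uptake, lay less than 1.5-fold lower; Igha was -0.90 against male control cells. Ramp1 (-0.76) and Rxrb (-0.61) lay at least 1.5-fold lower also with class shares held, and Wdr89 (-0.56) and Sdsl (-0.39) did not. The myosin light chain Myl10 had 184 and 48.8 CPM (-1.91), but only -0.41 against male control cells. The antibody light chain Iglc1 had 2670 and 104 UMIs (-4.84), and 10 cells held 94.1% of its control UMIs; for Igha 10 cells held 91.4%.

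**Figure D2:**
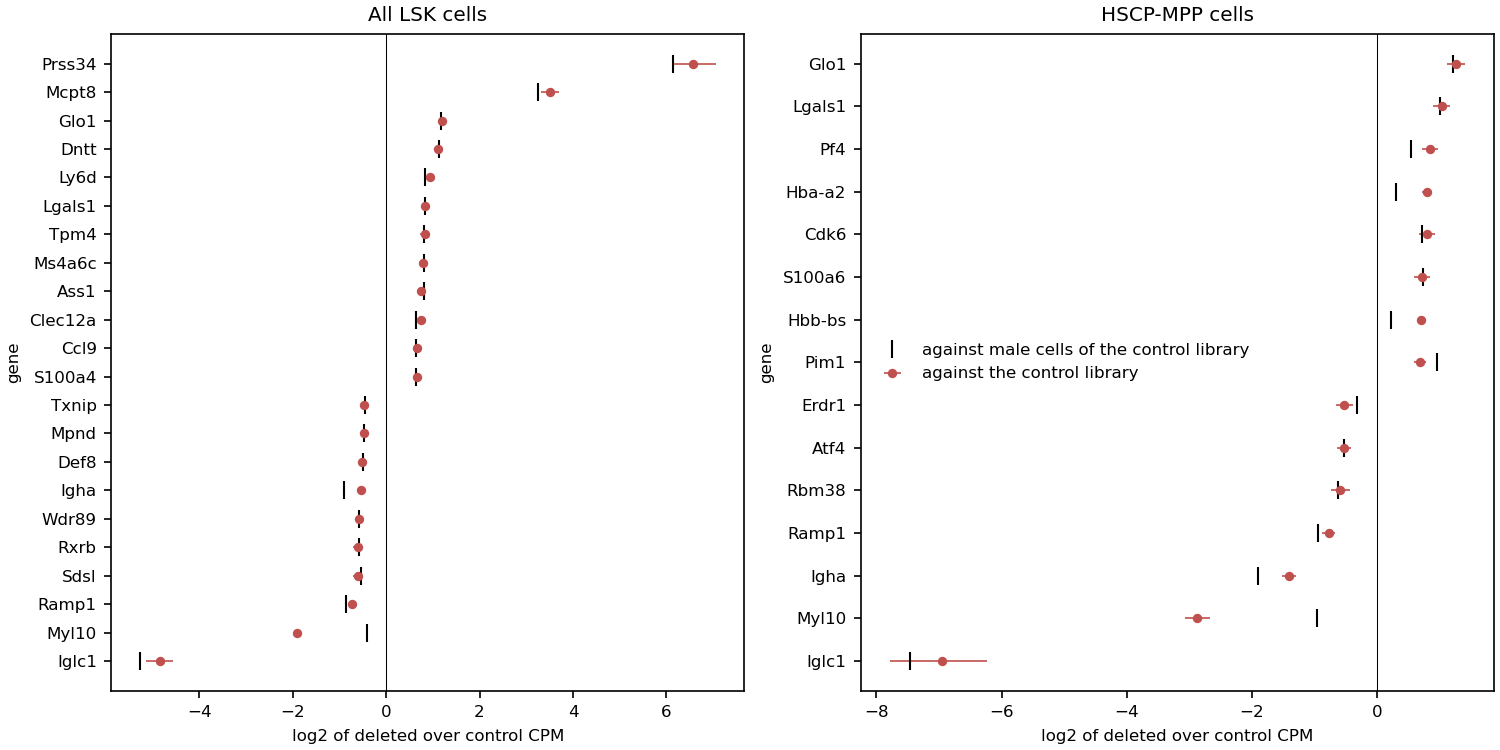
Log2 fold of deleted over control CPM (x axis) for genes named as the highest and lowest folds and reported here (y axis) in all LSK cells and in HSCP-MPP cells. Dots are folds against the whole control library with 95% counting intervals, and vertical ticks are folds against its male cells, which differ most for Myl10 in HSCP-MPP cells, at -2.87 and -0.96.

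Of the 46 gene lists, 39 had enough measured members in LSK cells; 9 medians lay above and 13 below the central 95% of random lists with the same expression, as a description of these libraries. Mitotic genes stood out on the upper side. The G2M list had a median log2 of 0.44 (0.39 to 0.46), with 43 of 44 members above 0 and 8 at least 1.5-fold higher, among them the ubiquitin-conjugating enzyme Ube2c (90.7 and 139 CPM), the spindle factor Tpx2 (21.5 and 33.1), Kif2c (6.2 and 10.2) and Lbr (51.7 and 80.1). With class shares held at those of the control, this median was 0.13. The S-phase list had a smaller median of 0.15, or 0.0736 with class shares held, with 34 of 40 members above 0, Tyms at 79.8 and 102 CPM and Rrm1 at 41.6 and 53.1. Lymphoid-primed markers had 0.39 (0.34 to 0.44), or 0.29 with class shares held, and all 12 measured members lay above 0, led by Dntt, Notch1 (17.4 and 27.9 CPM), Satb1 (41.2 and 62.2) and the antibody heavy chain Ighm (132 and 198). Dendritic markers had 0.47, or 0.24 with class shares held, with all 6 above 0, including Cox6a2 (19.4 and 48.5 CPM) and Cd74 (361 and 502). The Notch and Wnt list (0.33, 6 of 7 above 0), interferon gamma and MHC genes (0.19, 16 of 21), proteasome subunits (0.16, 36 of 38), histone genes (0.15, 14 of 24, but -0.0230 with class shares held) and the nuclear-encoded respiratory chain (0.09, 67 of 81) completed this side; the median over all measured genes was 0.05.

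HSC, erythroid-primed and granulocyte markers and the cholesterol synthesis and LXR target lists had the lowest medians. HSC markers had a median log2 of -0.37 (-0.41 to -0.29), and all 16 measured members lay below 0, with Mecom, a transcription factor of stem cells, at 48.6 and 35.0 CPM and Tcf15 at 13.2 and 8.98; with class shares held, the median was -0.12. The LXR target list had -0.28 (-0.37 to -0.19), or -0.24 with class shares held, with 8 of 9 members below 0. Its desaturase Scd2 had 36.7 and 20.1 CPM (-0.87), the trafficking GTPase Arl4c 29.8 and 16.2 CPM (-0.88) and Lpcat3, a phospholipid enzyme, 30.1 and 24.2 (-0.31). Apoe, a lipid carrier that is also on the erythroid-primed list, had 137 and 107 CPM (-0.36), but -0.10 with class shares held. The cholesterol synthesis list had -0.29 (-0.37 to -0.19), with 13 of 15 members below 0: Sqle, an early enzyme of the sterol branch, had 21.1 and 10.1 CPM (-1.06, -1.24 to -0.89), Insig1 13.7 and 9.46 (-0.53) and Cyp51 12.5 and 8.81 (-0.51), while Fdps was higher at 54.8 and 58.8 (0.10). Erythroid-primed markers had -0.36, or -0.11 with class shares held, with 5 of 5 below 0, Car2 at 489 and 360 CPM and the repressor Gfi1b at 13.1 and 7.45. Megakaryocyte-primed markers had -0.13, haematopoietic transcription factors -0.11, HSC ageing genes -0.09, immediate early genes -0.08, quiescence-associated genes -0.07, type I interferon genes -0.07, unfolded protein response genes -0.06 and ribosomal proteins -0.04. With class shares held, megakaryocyte-primed markers (0.0630) and quiescence-associated genes (0.0232) lay on the other side of 0, haematopoietic transcription factors (-0.0211), HSC ageing genes (-0.0172) and immediate early genes (-0.000935) lay near 0, and the unfolded protein response had -0.11. Against male control cells HSC ageing genes had -0.19, immediate early genes -0.18, and quiescence-associated and unfolded protein response genes -0.12 each. Granulocyte markers had -0.32, but 0.00416 with class shares held and -0.67 against male control cells. Their summed level was 3060 CPM in male and 351 CPM in female control cells. This too rested on few cells: 10 control cells held 45.8% of S100a8 and 56.2% of Ngp UMIs. The preNeu class, led by these genes, had 29 male and 0 female control cells.

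The other 17 lists lay within the range of random lists, with medians from -0.05 to 0.09. They were heat shock (0.05), Myc targets (0.07), glycolysis (-0.02), fatty acid oxidation with PPAR targets (0.01), the retinoic acid pathway (-0.05), RXR partner receptors (0.06), NF-kB (0.06), p53 targets (0.00), oxidative stress (0.02), TGF-beta (-0.02), cytokine receptors (-0.02), epigenetic regulators (0.07), autophagy (-0.02), apoptosis (0.06), mitochondrially encoded (0.04), Gimap (0.01) and myeloid-primed genes (0.09). The retinoic acid pathway (0.0641), TGF-beta (0.11), fatty acid oxidation (-0.0355), p53 targets (-0.00235) and myeloid-primed genes (-0.00526) lay on the other side of 0 with class shares held. Members of the retinoic acid list went both ways: Dhrs3, a retinaldehyde reductase, had 25.2 and 49.5 CPM (log2 0.97, 0.86 to 1.09), whereas the transglutaminase Tgm2 (11.3 and 5.69 CPM, -0.99) was lower.

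**Figure D3:**
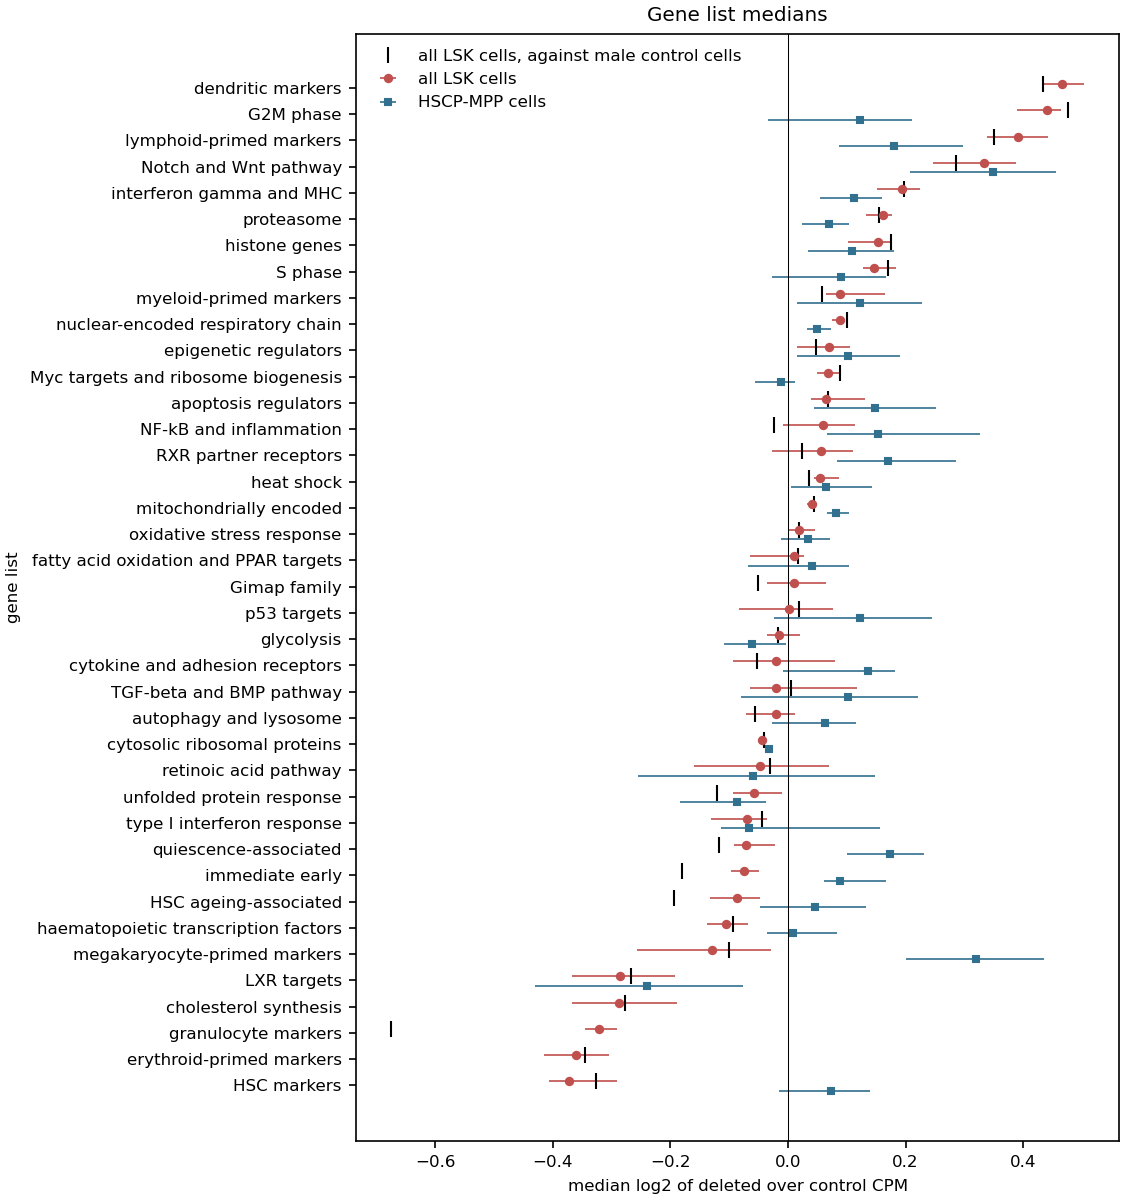
Median log2 fold of deleted over control (x axis) of gene lists (y axis) in all LSK cells and in HSCP-MPP cells, with 95% counting intervals; black ticks set the LSK cells against male control cells, and lists with too few measured members have no point. In LSK cells the G2M list lies at 0.44 and HSC markers lie at -0.37, while in HSCP-MPP cells HSC markers lie at 0.07.

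Marker sums of most other cell types also differed, but they do not count such cells alone, since some of these markers are leading genes of progenitor classes. Ccl5 is one in MPP Ccl3-high cells, and Trbc2, Ebf1, Vpreb1, Cox6a2 and Ly6d are in LMPP cells. Ccl5 alone gave 33.9 and 41.7 CPM of the T and NK sum. Summed mast and basophil markers had 18.2 and 206 CPM, monocyte and macrophage markers 531 and 734, dendritic markers 879 and 1195, T and NK markers 43.7 and 63.0 (54.0 in male control cells), B cell markers 43.8 and 59.6, and granulocyte markers 2416 and 1925. Mature erythroid markers had 945 and 992 CPM, but male control cells had 1230, which turns the direction. Either direction rests on few cells: 10 cells held 94.2% of control and 95.3% of deleted Hba-a1 UMIs. For Hbb-bs they held 91.5% and 94.2%. Endothelial and stromal markers had 26.3 and 21.1 CPM and innate lymphoid precursor markers 49.2 and 47.1, with no difference detectable at this depth (log2 -0.06, -0.15 to 0.03).

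Within HSCP-MPP cells, 16 of 2210 genes with at least 50 CPM lay at least 1.5-fold higher and 12 lower in the deleted library, and against male control cells 10 of the 16 and 9 of the 12 did so again. With totals that leave out mitochondrial and ribosomal genes these counts were 26 and 28, and female against male control cells of the class gave 7 and 20. Glo1 had 78.3 and 188 CPM (log2 1.27, 1.13 to 1.41), Lgals1 93.6 and 192 (1.03, 0.90 to 1.17), the cell cycle kinase Cdk6 111 and 193 (0.79, 0.67 to 0.92), S100a6 111 and 183 (0.71) and the kinase Pim1 179 and 288 (0.69, or 0.96 against male control cells). Lower were Ramp1 (330 and 194 CPM, -0.77) and the RNA-binding protein Rbm38 (135 and 89.7, -0.59), while the stress factor Atf4 (233 and 162, -0.53) and Erdr1 (-0.52, or -0.32 against male control cells) lay less than 1.5-fold lower. Myl10 stood at -2.87, and at -0.96 against male control cells. Platelet factor Pf4 (0.84), globins Hba-a2 (0.80) and Hbb-bs (0.71), and antibody chains Iglc1 (-6.95) and Igha (-1.41) rested largely on few cells. For Pf4, 10 cells held 75.3% of UMIs in the deleted and 44.6% in the control library. For each other of these genes, 10 cells held at least 92.8% of UMIs in either library. Against male control cells these 5 had 0.54, 0.30, 0.22, -7.46 and -1.90. In HSC-like cells of the own clusters at resolution 0.8, Pf4 (-0.64), Hba-a2 (-0.32) and Hbb-bs (-0.43) were lower instead. With sub-cluster shares held at those of the control, Pf4 (1.51), Hba-a2 (1.11) and Hbb-bs (1.01) were higher. Rxrb in this class had 46.4 and 29.6 CPM (-0.65, -0.91 to -0.39). The make-up of the class also differed by the authors' sub-clusters. High-output_Rodriguez_c7, led by Plac8 and Cd48, took 26.4% of its control cells and 37.0% of its deleted cells, a ratio of 1.40 (1.21 to 1.63). Against male control cells the ratio was 1.57 (1.33 to 1.87). In the control it took 23.5% of male and 34.7% (29.7 to 40.0) of female cells, and the deleted share lay within the female interval. Sizes of the other 3 were not compared, since their leading genes differed, a rule set after the shares were seen. Among these, High-output_Rodriguez_c6 held 474 of 1319 control and 173 of 960 deleted cells, or 35.9% and 18.0%. Shares within the class depend on each other, so the lower share of c6 by itself raises those of the others, c7 included. High-output_Rodriguez_c7 held 348 control and 355 deleted cells, and its higher share is not read as a growth of these cells. With sub-cluster shares held at those of the control, 15 genes lay at least 1.5-fold higher and 11 lower.

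Among lists in HSCP-MPP cells, 34 had enough members, 4 lay above and 5 below the random range. Megakaryocyte-primed markers had a median log2 of 0.32 (0.20 to 0.44), or 0.53 with sub-cluster shares held, with Vwf at 19.7 and 29.5 CPM and Cd9 at 81.1 and 105, and they lay below 0, at -0.05, in cells chosen instead by Hlf, Mecom and Procr. The Notch and Wnt list had 0.35, with the transcription factor Myb at 83.0 and 106 CPM. Quiescence-associated genes had 0.17 (0.10 to 0.23), with 15 of 21 above 0, the cell cycle inhibitor Cdkn1a at 48.5 and 76.9 CPM and Zfp36l2 at 239 and 353; against male control cells the median was 0.05, and with sub-cluster shares held 0.0595. Interferon gamma and MHC genes had 0.11, with H2-Aa at 71.6 and 105 CPM. LXR targets had -0.24 (-0.43 to -0.08), -0.17 against male control cells and -0.46 with totals that leave out mitochondrial and ribosomal genes, with 5 of 6 below 0, Scd2 at 36.3 and 18.5 CPM (-0.97, -1.30 to -0.66) and the cholesterol exporter Abcg1 at 22.1 and 12.6 (-0.81, -1.22 to -0.42). The unfolded protein response (-0.09), glycolysis (-0.06), ribosomal proteins (-0.03) and Myc targets (-0.01) were the other lists on the lower side; in the cells chosen by Hlf, Mecom and Procr the unfolded protein response (0.0539) and glycolysis (0.0490) lay above 0, as did Myc targets (0.0246) against male control cells. HSC markers (0.07), S-phase (0.09) and G2M genes (0.12) lay within the random range, and cholesterol synthesis had too few members measured.

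In the 5 other classes with at least 100 cells per library, the pattern of lower stem cell and higher lymphoid markers recurred. HSC marker medians lay from -0.37 in Mitotic M-M-G1 to -0.13 in MPP Ier3-high cells, and lymphoid-primed medians from 0.24 in MPP Ier3-high to 0.36 in S-phase cells, each outside the random range. LXR target medians were -0.58 (-0.79 to -0.31) in MPP Ccl3-high, -0.48 (-0.66 to -0.29) in M-phase, -0.33 (-0.47 to -0.25) in S-phase and -0.31 (-0.56 to 0.04) in Mitotic M-M-G1 cells, where the interval crosses 0, and -0.12 (-0.35 to 0.01) in MPP Ier3-high cells, within the random range. Glo1 lay at least 1.5-fold higher in all 6 compared classes, from log2 1.12 in MPP Ccl3-high to 1.27 in HSCP-MPP and MPP Ier3-high cells. Lgals1 was also higher in S-phase (1.04), MPP Ier3-high (1.13), MPP Ccl3-high (0.96) and M-phase cells (0.84), and Dntt in S-phase (0.70), M-phase (0.72) and Mitotic M-M-G1 cells (1.22). Only classes where the gene was among the 4 highest folds are listed. Dntt also had 590 and 794 UMIs in 722 and 543 MPP Ier3-high cells, and 571 and 1090 UMIs in 604 and 611 MPP Ccl3-high cells. Lgals1 had 821 and 2352 UMIs in 182 and 260 Mitotic M-M-G1 cells. MPP Ccl3-high cells also had higher MHC class II genes, Cd74 at 148 and 373 CPM (1.33) and H2-Eb1 at 41.7 and 104 (1.32), of which 10 deleted cells held 57.2% and 56.1%, and a lower Ccl5 (-1.29), of which 10 cells held 95% in the control. Ass1 in S-phase (0.68) and Ighm in M-phase cells (0.67) were higher.

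Numbers of genes at least 1.5-fold higher and lower were 8 and 13 in S-phase, 22 and 15 in MPP Ier3-high, 24 and 9 in MPP Ccl3-high, 8 and 12 in M-phase and 37 and 29 in Mitotic M-M-G1 cells. Female against male cells of the control library alone, with fewer cells, gave 5 and 11, 33 and 73, 21 and 45, 15 and 21, and 75 and 63 in the same order. Genes of basophils, plasma cells, erythroid cells and neutrophils took the outermost places in several classes and rested on few cells. In MPP Ier3-high cells Prss34 had 0 and 1616 UMIs, Mcpt8 had 4.97 and 208 CPM, and Ighg2b (-5.62), Hba-a1 (-5.15), Hba-a2 (-5.02) and Hbb-bs (-4.79) were lower; 10 deleted cells held 97.2% of the Prss34 UMIs, and 1 control cell had at least 10 Hba-a1 UMIs. M-phase cells had lower neutrophil granule genes, Ngp (-4.11), Camp (-3.82), S100a8 (-3.35) and S100a9 (-3.09), and 3 control cells had at least 10 Ngp UMIs. In Mitotic M-M-G1 cells Prss34 had 0 and 577 UMIs, Mcpt8 had 12.9 and 132 CPM, and Igkc was -2.56 but 0.11 against male control cells, beside lower Lgals3 (-1.21) and lysozyme Lyz2 (-1.10), which were -0.59 and -0.81 against male control cells. Myl10 (-1.80 in S-phase cells, but -0.23 against male control cells), Ramp1 (-0.83 in S-phase cells and -0.58 in MPP Ccl3-high cells), Wdr89 (-0.60 and -0.59 there) and Erdr1 (-0.46 in S-phase cells) were the other low genes of these classes; Erdr1, and Ramp1 in MPP Ccl3-high cells, lay less than 1.5-fold lower.

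**Figure D4:**
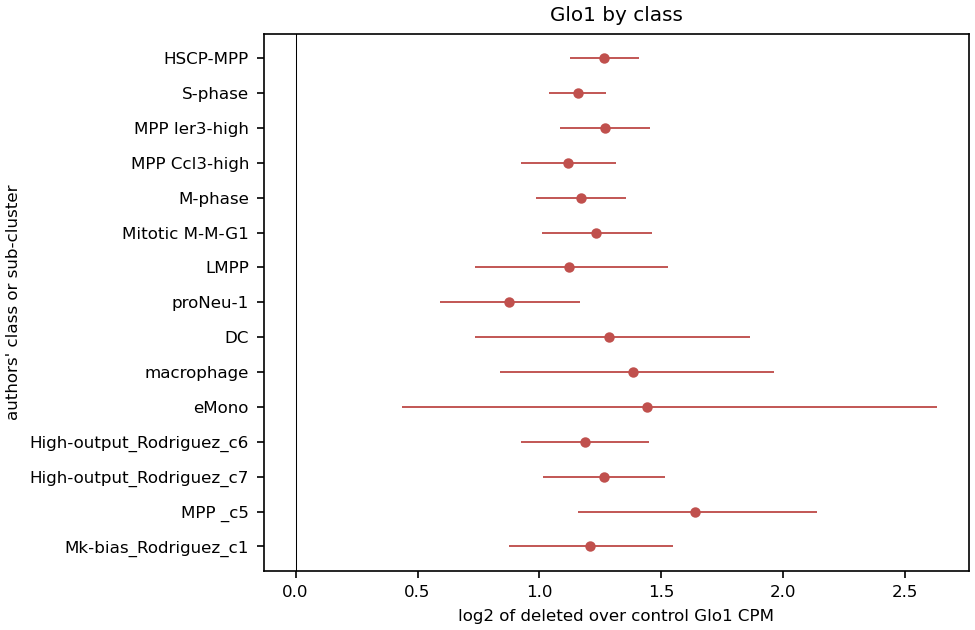
Log2 fold of deleted over control Glo1 CPM (x axis) in each of the authors' classes and sub-clusters (y axis), with 95% counting intervals; preNeu cells, with 0 control UMIs, are left out. All 15 plotted folds lie above 0, from 0.87 in proNeu-1 to 1.64 in MPP _c5 cells. MPP _c5 is the authors' name, and its leading genes are antibody chains, Jchain, Mzb1, Cd74 and H2-Aa.

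More cells carried cell cycle transcripts in the deleted library over the whole gate. With each cell thinned to 3000 UMIs, 34.5% of control and 40.0% of deleted cells exceeded the limit of the S-phase list, a ratio of 1.16 (1.08 to 1.24), and 30.9% and 37.7% that of the G2M list, a ratio of 1.22 (1.13 to 1.31). Without thinning the ratios were 1.2 and 1.28. The G2M list took 3256 and 4055 CPM and the S-phase list 2330 and 2555 CPM. Within HSCP-MPP cells no difference in these shares was detectable at this depth: 7.25% and 7.84% exceeded the S-phase limit (ratio 1.08, 0.79 to 1.48) and 6.87% and 7.63% the G2M limit (1.11, 0.80 to 1.53). Without thinning those ratios were 0.978 and 1.45. Summed CPM was slightly higher in the class, at 1015 and 1059 for the S-phase list (log2 0.06, 0.01 to 0.11) and 1180 and 1221 for the G2M list (0.05, 0.01 to 0.09). Of its sub-clusters, High-output_Rodriguez_c6, with 474 control and 173 deleted cells, led by globins and Pf4 and with its leading genes Pf4, Cd9 and Myl10 apart between the libraries within sub-clusters, had log2 folds of 0.29 (0.20 to 0.38) and 0.21 (0.13 to 0.29) for these lists, and the intervals of the others included 0. LMPP cells, fewer than 100 in the control, went the other way in summed CPM, with log2 folds of -0.16 (-0.24 to -0.08) and -0.23 (-0.31 to -0.15). Of them, 29.2% (20.1 to 39.8) and 19.9% (15.1 to 25.5) exceeded the G2M limit, again with overlapping intervals. For the G2M list the deleted cells had 1939 CPM, beside 2271 in all and 1976 in male control cells of the class. Shallower cells left out numbered 49 in the control and 11 in the deleted library, and free RNA, which such limits also read, was not measured.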

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

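The comparisons with male control cells, with own clusters at resolution 0.8, with sub-cluster shares held and without the 4% of cells with the highest doublet scores were chosen only after the data were seen; the other alternatives were planned. Keeping called doublets could not be run as an alternative, because none were called. No paired analysis was possible because each group has 1 library. Over 1308 recomputed values, the main results gave 188 within their counting interval or within 1.5 times the count, 57 outside it and 3 with the other sign, and the single genes and remaining lists gave 796, 243 and 21. The other sign is counted here only where the main value differs by its counting interval and, for a list, lies outside the random range; 83 further values, 2 of them of main results, also lay on the other side of no difference. Depth limits Rxra and Rxrg, at 84 and 1 control UMIs, and the cell cycle shares of HSCP-MPP cells.

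The HSCP-MPP and LMPP share ratios kept their direction in all settings run. HSCP-MPP or HSC-like cells had 0.839 with own clusters at resolution 0.8 and 0.882 when genes were scaled within libraries. Own clusters separated cells partly by sex. At resolution 0.8 an unnamed cluster led by Xist and Myl10 held 368 control and 4 deleted cells, and at resolution 1.2 a like cluster held 450 and 11. The first took 189 HSCP-MPP cells. Such control cells are left out of the HSC-like count, which raises its ratio. LMPP or lymphoid-primed-like cells had 1.44 at resolution 0.5, 1.48 at resolution 1.2, 1.98 with another seed, 1.23 scaled within libraries, 1.68 without phase and differing genes, 1.83 over all barcodes and 1.25 with the strict cell filter. Numbers of higher and lower LSK genes were 8 and 8 by a 2-fold rule, 123 and 95 with a floor of 5 CPM, and 10 and 5 with a floor of 100 CPM; a lower floor admits more genes. Class-standardised, 21 were higher, and with totals without mitochondrial and ribosomal genes, which raise the CPM of all other genes against the floor and also shift the folds, 57 were lower. In HSCP-MPP cells they were 2 and 6 by the 2-fold rule, 41 and 35 at 20 CPM, 10 higher at 100 CPM, 26 and 28 with those smaller totals, and 6 lower at resolution 0.5. The S-phase class had 8 lower genes against male control cells.

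Among LSK list medians, the S-phase list had 0.13 with TMM factors, 0.20 thinned to 3000 UMIs, 0.11 with totals without mitochondrial and ribosomal genes and 0.0736 class-standardised. The G2M list had 0.39 thinned, 0.48 against male control cells and 0.13 class-standardised. HSC markers had -0.22 thinned, -0.25 as a mean over cells, -0.28 with members from 2 CPM, -0.42 with the smaller totals and -0.12 class-standardised. Lymphoid-primed markers had 0.29 class-standardised. Cholesterol synthesis had -0.39 thinned and -0.40 as a mean over cells. Quiescence-associated genes had -0.12 against male control cells, -0.11 with the smaller totals and the other sign, 0.0232, class-standardised. Class-standardised values of histone genes (-0.0230), megakaryocyte-primed (0.0630) and granulocyte markers (0.00416) also changed sign, as did granulocyte markers thinned (0.0566) and histone genes from 2 CPM (-0.00730). Against male control cells the summed markers had log2 folds of 0.22 for T or NK cells, -0.67 for granulocytes and 0.32 for monocytes or macrophages. Mast cells or basophils had 3.20 and, with the other sign, mature erythroid cells had -0.31. Globins and basophil proteases rested largely on few cells, and granulocyte genes in part. For these shifts the cause was not tested, except that class-standardised values remove the difference in class shares.

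In HSCP-MPP cells, quiescence-associated genes had 0.0541 against male control cells, 0.0563 in cells with UMIs of 2 of Hlf, Mecom and Procr, 0.0795 in own clusters at resolution 0.8 and 0.0595 with sub-cluster shares held. LXR targets had -0.46 with the smaller totals. Megakaryocyte-primed markers had 0.53 with sub-cluster shares held, 0.0815, 0.0644, 0.12 and 0.0717 in own clusters at resolutions 0.8, 0.5 and 1.2 and scaled within libraries, and -0.0549 in the Hlf, Mecom and Procr cells, where glycolysis (0.0490) and the unfolded protein response (0.0539) also changed sign. Pf4 had -0.74 and Hbb-bs -0.59 in those cells. Own clusters turned Pf4 to -0.64, -0.45, -0.58 and -0.65, Hba-a2 to -0.32, -0.24, -0.56 and -0.61 and Hbb-bs to -0.43, -0.57, -0.29 and -0.41 at resolutions 0.8, 0.5, 1.2 and scaled within libraries. With sub-cluster shares held, Pf4 had 1.51, Hba-a2 1.11 and Hbb-bs 1.01. These genes rest largely on few cells, less so for Pf4 in the control. At resolution 0.8 an own cluster named mature erythroid-like, with the globins and Pf4 among its leading genes, took 90 HSCP-MPP cells. Those cells thus lay outside the HSC-like cells. Clusters with the same leading genes were also named so at resolutions 0.5 and 1.2. The single cells that held most of the UMIs were not followed.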

Other observations

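The tests below were chosen only after the result was seen, except the test of the cholesterol synthesis list against a shift in cell classes. Some surface proteins and other genes also differed in LSK cells. Cd48, which stem cells lack and committed multipotent progenitors carry, had 99.7 CPM in the control and 151 CPM in the deleted library (log2 0.60, 0.54 to 0.65). Ly6a, which codes for the Sca1 used in the sort, had 67.7 and 51.1 CPM (-0.41, -0.49 to -0.32), and Eng had 51.2 and 38.9 CPM (-0.39). Plac8 was higher at 1387 and 2016 CPM (0.54) and Irf8, a factor of dendritic and monocyte fate, at 114 and 167 CPM (0.55). Of the glycolysis list, Aldoc had 10.3 and 3.78 CPM (-1.45, -1.73 to -1.18), while Gapdh had 1794 and 1929 CPM (0.11). With class shares held at those of the control, the log2 folds were 0.43 for Cd48, -0.29 for Ly6a, -0.26 for Eng, 0.34 for Plac8, 0.18 for Irf8, -1.33 for Aldoc and 0.0677 for Gapdh.

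Within HSCP-MPP cells, single members of several lists stood apart too. Dhrs3, a retinaldehyde reductase, had 14.8 and 27.2 CPM (0.87, 0.53 to 1.22), and the interferon-induced GTPases Gbp2 and Igtp had 15.6 and 29.0 CPM (0.90) and 13.9 and 22.1 CPM (0.67). Plk2 had 27.6 and 16 CPM (-0.78, -1.14 to -0.43). Procr and Mllt3, both stem cell markers, had 92.0 and 115 CPM (0.32) and 105 and 133 CPM (0.35), and Meis1 had 180 and 154 CPM (-0.22).

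The LMPP share was higher in the deleted library. Against male control cells the ratio was 2.89 (2.2 to 3.83), which argues against female cells of the control as its cause. In the 8 own clusterings the ratio of lymphoid-primed-like cells lay between 1.23 (1.10 to 1.38) and 2.22, but the markers that name these clusters were themselves higher within classes, so more such cells and higher lymphoid genes in similar cells cannot be told apart this way. The rule that names those clusters was also set after cell counts per library had been seen. Loss of the receptors may have raised this share, but with 1 library per group a difference between mice, sorts or litters was not tested and stays open.

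Glo1 was higher in the deleted library by a similar factor across classes, from log2 1.12 to 1.27 in the larger ones. In the 6 classes with at least 100 cells per library the lowest lower bound of its log2 fold was 0.92, and the class-standardised fold was 1.19, which argues against a shift in cell classes. The other 4 genes at 5 CPM or more within 500 kb of Glo1 had a median log2 of 0.22, with Btbd9 at 0.51 (0.39 to 0.63), Dnah8 at 0.32 (0.05 to 0.60), 1700097N02Rik at 0.11 and Abcg1 at -0.28. A candidate explanation is a segment of chromosome 17, which also carries Rxrb, that differs between the mice, since some inbred strains carry a duplication around Glo1. Mice of both libraries had the floxed Rxrb allele, so carrying that allele does not set the libraries apart. The neighbours are few and go both ways. Abcg1, the lower one, starts 472739 bp from Glo1, near the edge of the window, and is also on the LXR target list that was lower. It therefore says little against a shorter segment, and the nearer genes had log2 folds from 0.11 to 0.51. Such a segment and an effect of the receptors thus cannot be told apart.

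The cholesterol synthesis list was lower in the deleted library. With class shares held at those of the control its median log2 over the 15 members measured in the pooled cells was -0.35 (-0.43 to -0.25), beside -0.29 in the pooled cells (-0.36 with members chosen by class-standardised CPM), and against male control cells it was -0.28 (-0.39 to -0.20). Both argue against class shares or female cells as the whole cause. An effect of the receptors and differences between mice were not tested and stay open.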
